A study of Drosophila melanogaster with 2 samples.

How the data were processed

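Binding of emc fused to eGFP was measured by chromatin immunoprecipitation and sequencing in 2 samples of whole embryos, biological replicates 1 and 3 of 1 group. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an antibody against GFP, and the embryos were 0 to 24 h old. The labels call the replicates biological but do not describe separate collections, so the spread between them may be partly technical.

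The authors deposited peak lists in narrowPeak format on dm6 and dm3. Each replicate had a relaxed list of peaks and background made as input for the IDR procedure, and the series had a pooled relaxed list and an IDR-thresholded list. Per the listing files deposited with the samples, both replicates used the same control alignment, and that control library was not analysed here. The aligner, the peak caller, the IDR cutoff and their versions are not given in the sources used here. The signal of each peak is the value the authors deposited in the signal column of narrowPeak, scaled by their caller, and it was used only to rank and describe peaks. The authors also deposited a −log10 q-value per peak, which broke ties in ranking, and no p-value. Each replicate list held exactly 30000 peaks, so its lower end was set by number. The IDR list was pooled over replicates, and 1865 of 1865 of its peaks matched a pooled peak of equal position and signal. In 90.2% of IDR peaks the summit was the midpoint of the interval to within 1 bp.

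All computations started from these lists, with dm6 as the main build and no conversion of coordinates. Sequence was the Release 6 assembly, and genes came from Ensembl release 115 (annotation 6.54). Peaks on 2L, 2R, 3L, 3R, 4 and X were used. Peaks were called overlapping from 1 bp. Summits were put in 1 of 7 classes in the order promoter (within 500 bp of a TSS of a protein-coding or non-coding RNA gene), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. The non-coding exon class was added to the planned scheme, because its summits had no place there. A gene was occupied if a summit lay within 1000 bp of any of its starts. The 15 gene lists were fixed before the data were examined, and 5 symbols were renamed to those of the annotation. Motifs were searched on both strands in windows of 201 bp.

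Shares were compared with weaker peaks or other genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within classes, lists or motifs. Medians of signal and means of GC were compared by permutation with 100000 permutations, and 1000 random placements per chromosome gave a further background. Peaks and genes are not independent replicates, so these tests describe this set of peaks. With 2 replicates in 1 group no test between groups was possible. GC matching drew 3 weaker peaks per IDR peak in bins of 2.5% GC and kept 1864 IDR peaks, and among promoter peaks 1056. Lists matched on TSS number and gene length were drawn 10000 times. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

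The steps were tested on simulated data. A planted promoter share of 60% among 1865 peaks was recovered at a mean of 60.0% and called in 100 of 100 runs, and with no planted difference 2 of 100 runs were called. A list planted at 60% occupancy was called in 100 of 100 runs over 13945 genes, and lists without a difference in 5 of 1400 tests. DRE planted in 5% of windows was called in 100 of 100 runs and other motifs in 3 of 1500 tests. With windows drawn to be poorer in GC, 825 of 1600 motif tests were called before matching and 5 of 1600 after it.

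Named genes were emc, the genes nearest to the 15 strongest IDR peaks, up to 4 occupied members with the highest signal of each list past an adjusted p of 0.05 and up to 2 of each other list, and the 5 genes with the most IDR peaks. Ties were all named. Alternatives covered the build, the overlap rule, a stricter set (the 932 IDR peaks of higher signal), the 1865 top-ranked peaks of either replicate alone, other windows and other backgrounds. Those chosen after seeing the data were the GC-matched promoter peaks for motifs, GC matching for all genomic classes, random placements and the 1865 weaker peaks of highest signal for classes other than promoters, equal windows for tRNA genes, and 2 trimmed gene lists. The cuticle list is every symbol that starts with Cpr and a digit.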

Results

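Chromatin immunoprecipitation with an antibody against GFP was sequenced from whole embryos of Drosophila melanogaster aged 0 to 24 h, of both sexes together, that carried extra macrochaetae (emc) fused at its C-terminus to eGFP. The emc protein has a helix-loop-helix dimerization domain but lacks the basic region with which related proteins touch DNA, and its best-known partner is the class I bHLH protein Daughterless. All samples formed 1 group of 2 biological replicates, numbered 1 and 3, with no control library among the samples, so the comparisons are between replicates and between classes of peaks or genes. Each replicate list held 30000 peaks in dm6, the pooled list 29400 and the list that passed the authors' threshold on the irreproducible discovery rate (IDR) 1865. Read depth was not given in the files, and no depth per library could be stated. Peaks of the pooled list that overlapped no IDR peak, 27229 in number, are called weaker peaks below. The authors describe the pooled list too as peaks and background. Its lowest −log10 q was 0.0178, against 2.79 in the IDR list. Weaker peaks may therefore include background regions, which were not separated here. Coordinates are dm6 and 1-based, and shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

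The first question was how far the 2 replicates marked the same places. Nearly all of the strong peaks were shared, and the weak ones mostly were not. The peaks near CG14100 and Ugalt, a UDP-galactose transporter, ranked 1 and 2 in both replicates. Of the 1865 top-ranked peaks of replicate 1, 97.7% (interval 96.9 to 98.3) overlapped a replicate 3 peak, and in the opposite direction it was 1790 of 1865, 96.0%, against a mean of 15.1% and 15.7% for 1000 random placements. Restricted to the top-ranked peaks of both lists, the shares were 70.1% and 70.9%, against a random mean of 0.977% and 0.994%. Over the full lists the shares were 41.9% and 44.3%, against a random mean of 15.4% and 16.0%. Among peaks ranked beyond 20000 they were 28.7% and 30.8%, also above those means, although random placements were not made for these ranks apart. Across the 1854 IDR peaks in both lists signal correlated with a Spearman rho of 0.622 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The Pearson r was 0.738 on the log2 scale, for which no p was computed. The IDR peaks were the pooled peaks of highest signal, above a threshold on reproducibility between these replicates. Both correlations are therefore over a selected range of signal. Over all 12580 overlapping replicate peaks rho was 0.484 and r 0.723. Peaks are not independent replicates.

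**Figure D1:**
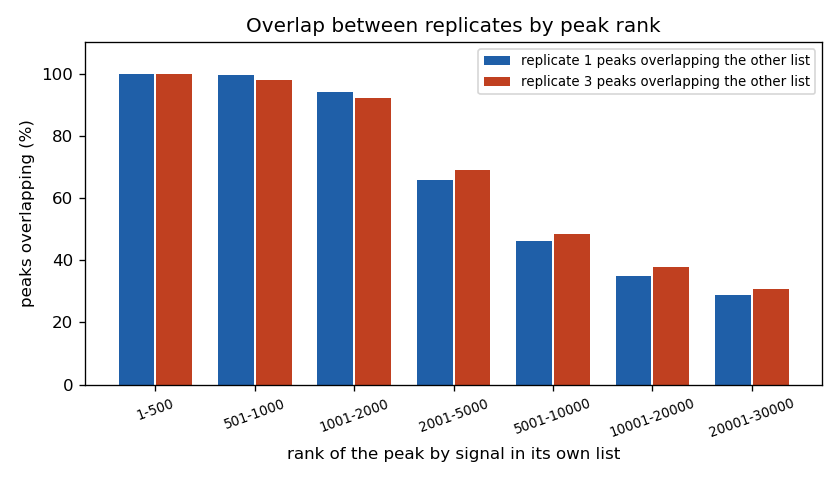
Share of peaks (%) that overlap a peak of the other replicate by at least 1 bp, by the rank of the peak in its own list, for replicate 1 and replicate 3. The share is 100% and 99.8% for ranks 1 to 500 and 28.7% and 30.8% for ranks beyond 20000.

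The strongest IDR peaks lay at genes of several unrelated functions. The highest signal, 1207, was at 3L 19590449 to 19590786, 98 bp from the start of CG14100, and the next, 1179, was at X 2703722 to 2704063, 38 bp from the start of Ugalt. The peak ranked 3 (signal 871, 2L 480922 to 481262) lay in an intron of ush, with the zinc finger gene cbt as the nearest start at 1415 bp. The peak ranked 5 (signal 806, 2R 15217604 to 15217906) was 139 bp from mRpL41, a mitochondrial ribosomal protein gene. The peak ranked 7 (signal 671, 3R 15229362 to 15229687) lay between the divergent genes Art3, an arginine methyltransferase, and mRpS10, at 109 and 148 bp. Promoter peaks at px, ph-p (a Polycomb group gene), PNPase, CG1888, Shc and Chro (a chromodomain protein) had signals of 655, 651, 650, 613, 602 and 589. The Shc peak also lay within 500 bp of a start of Atat, and the Chro peak within 500 bp of a start of Ssl1. Peaks in introns of CG11050, the kinase gene Lk6 and CG32772 had signals of 816, 657 and 574. The remaining peak of the top 15 (signal 701) was 5097 bp from CG4004, and 453 bp from the start of a long non-coding RNA. The IDR list was the 1865 pooled peaks of highest signal, the lowest at 62.7, with a median width of 380 bp. The dm3 list held 1852.

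IDR peaks lay mostly at promoters and almost never in coding exons outside promoters. A summit within 500 bp of an annotated transcription start site (TSS) was found for 1136 of 1865 IDR peaks, 60.9% (58.7 to 63.1), against 25.3% of weaker peaks and a mean of 13.2% for random placements. Coding exons farther than 500 bp from any TSS held 8 IDR summits, 0.429% (0.185 to 0.843), against 20.5% of weaker peaks and 13.7% of random placements. Coding summits nearer to a TSS were classed as promoter in every set and were not counted apart. Introns held 528 (28.3%, against 33.3%) and intergenic sequence 164 (8.79%, against 16.5%). Against the 1865 weaker peaks of highest signal alone the differences were smaller, with 50.8% in promoters (1.20-fold) and 3.06% in coding exons (0.140-fold), both still past the threshold, and the calls for introns, the 3' UTR and non-coding exons were lost (adjusted p = 0.127, 0.127 and 0.150, Fisher's exact test). For classes other than promoters this background was chosen after seeing the data. The 5' UTR, 3' UTR and non-coding exon held 10, 11 and 8 summits. By two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 7 classes, the adjusted p was 2.13e-213 for promoters, 2.05e-162 for coding exons, 1.81e-20 for intergenic sequence and 1.03e-05 for introns. The classes are parts of a whole, so the excess in promoters lowers the shares of the others. Outside promoters, introns held 528 of 729 IDR summits and 9071 of 20353 weaker summits, a higher fraction for IDR peaks. Intergenic sequence held 164 and 4488 of these, which are similar fractions, and coding exons 8 and 5584. These fractions were not tested. The lower shares in the 5' UTR and in non-coding exons (adjusted p = 0.0036 and 0.0171, Fisher's exact test) lay within the range of random placements, and both calls were lost among the 932 IDR peaks of higher signal and in the top-ranked peaks of replicate 1 alone. In the latter the share of coding exons was 1.23%.

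**Figure D2:**
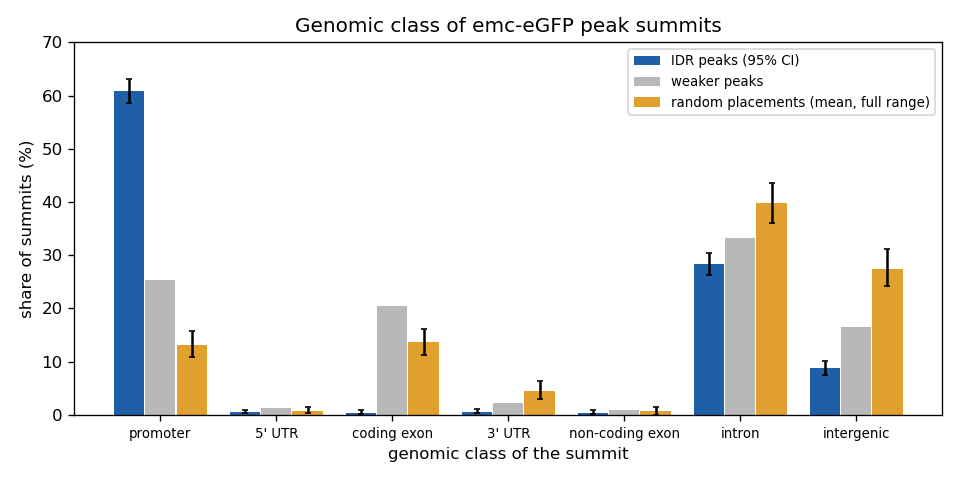
Share of summits (%) in each genomic class for 1865 IDR peaks (bars with 95% intervals), 27229 weaker peaks and random placements (mean and full range of 1000). Promoters hold 60.9%, 25.3% and 13.2%, and coding exons outside promoters 0.429%, 20.5% and 13.7%.

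Promoter peaks had slightly higher signal than the other IDR peaks. The median signal was 97.2 at 1136 promoter peaks (quartiles 74.5 and 138) and 90.2 at 729 others (72.2 and 121), a difference of 6.94 (two-sided permutation test, 100000 permutations, p = 0.00472). The quartile ranges overlapped over most of their length. The signal is the authors' own value for each peak.

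The X chromosome was compared with the large autosome arms because embryos of both sexes were pooled. It held 350 of 1856 such IDR peaks, 18.9% (17.1 to 20.7), or 14.9 per Mb against 13.8 per Mb on 2L, 2R, 3L and 3R. That share was above the 14.2% of weaker peaks (two-sided Fisher's exact test, p = 1.24e-07). It was not distinguishable from the 17.8% of sequence length (exact binomial test, p = 0.224). With both sexes pooled, X was present in fewer copies than the autosomes, which sequence length does not take into account. The length test therefore cannot say whether X peaks were in excess per copy. Chromosome 4 held 9 IDR peaks.

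Among the 15 gene lists, cytoplasmic ribosomal protein genes stood out. Of these 92 genes, 59 had an IDR summit within 1000 bp of a TSS, 64.1% (53.5 to 73.9), against 12.0% of other protein-coding genes, a 5.33-fold difference. The call was kept in every alternative. The fold ranged from 2.98 within 5000 bp of a TSS (70.7% against 23.7%) to 7.14 among the 932 IDR peaks of higher signal. The median of the best signal was 134, and the median distance to a TSS was 32 bp. RpS27 (signal 510, 3R 25247400 to 25247652), RpL7 (423), RpL23A (360) and RpL14 (266) had the highest signals. Of the 59 genes, 51 were also occupied by the top-ranked peaks of each replicate alone. The list includes pairs of similar copies, such as RpS14a and RpS14b, whose peaks are uncertain where reads could be shared.

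Chemoreceptor and cuticle genes almost all lacked IDR summits within 1000 bp of a TSS. Among chemoreceptor genes 1 of 179 was occupied, 0.559% (0.0141 to 3.07), and that gene, Or9a, had its summit at 992 bp, within 500 bp of the start of Neb-cGP. None of 70 cuticle (Cpr) genes was occupied, with an upper limit of 5.13%. Within 5000 bp of a TSS 13 chemoreceptor genes (7.26%, against 24.2% of other genes) and 5 cuticle genes (7.14%, against 24.1%) were occupied, with both calls kept. The adjusted p from two-sided Fisher's exact tests over the lists was 3.06e-30 for ribosomal protein genes, 1.33e-08 for chemoreceptor genes and 0.000829 for cuticle genes. Among the 932 IDR peaks of higher signal the call for cuticle genes was lost, with an adjusted p of 0.0709 against 0.00138 to 0.0299 in the other alternatives (Fisher's exact or matched-list permutation test).

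The Notch pathway core also passed, with 7 of 18 genes (38.9%, 17.3 to 64.3; 3.15-fold; adjusted p = 0.0152, Fisher's exact test). The 4 with the highest signal were gro, a corepressor (207, 3R 26042440 to 26042549), aph-1, a subunit of gamma-secretase (143), numb (82.6) and dx (81.4). The dx peak lay 8 bp from the start of the neighbouring RpL7A, so 1 peak counted for both lists. The peaks of kuz and Nct were within 500 bp of B4 and CG7006, not of their own starts. This call was lost in each of the 7 alternatives tried, with an adjusted p of 0.0583 to 0.666 by Fisher's exact or the matched-list permutation test, and the fold ranged from 1.67 among the 932 IDR peaks of higher signal to 2.77 with the top-ranked peaks of replicate 1 alone.

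No other list passed. In the list of emc and 22 bHLH genes 2 were occupied, da, which encodes Daughterless (signal 70.7, 67 bp), and emc (68.1). With the top-ranked peaks of replicate 3 alone none was. E(spl)m3-HLH (91.8) was the single one of 19 E(spl), Hairy and Bearded-family genes, bcd (80.8) of 28 segmentation genes, brk (146) of 24 dorsoventral and mesoderm genes, elav (166) of 18 neuronal and glial genes and sls (153) of 13 muscle genes. The brk summit lay in an intron of CG1677, 771 bp from the start of brk, and within 500 bp none of those 24 genes was occupied. Among 19 gut, tracheal and renal regulators fkh (125) and bowl (103) were occupied, and none of 8 Hox genes was, with an upper limit of 36.9%. Mitochondrial ribosomal protein genes reached 12 of 73 (16.4%; adjusted p = 0.711, Fisher's exact test), with mRpL41 and mRpS10 on top. That list passed against random lists matched on TSS number and gene length (2.37-fold; adjusted p = 0.0277, permutation), and within 5000 bp of a TSS (37.0%, 1.54-fold; adjusted p = 0.0388, Fisher's exact test), while the adjusted p over its other alternatives was 0.308 to 0.982. By nearest TSS its share was 6.85%, below other genes. Except at mRpL41, the summit at each occupied gene of this list also lay within 500 bp of the start of another gene. The matched lists did not take such neighbours into account. Of 14 heat shock genes 3 were occupied, Hsp83 (194) and Hsp27 (183) with the highest signal, and within 5000 bp of a TSS the share was 57.1% (adjusted p = 0.0299, Fisher's exact test). In windows this wide 1 summit can count for neighbouring genes, which was not examined, and the test treats genes as independent. The chorion and yolk list had 1 of 14, Cp190 (139), which matched its symbol pattern but encodes a chromatin insulator and centrosomal protein.

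**Figure D3:**
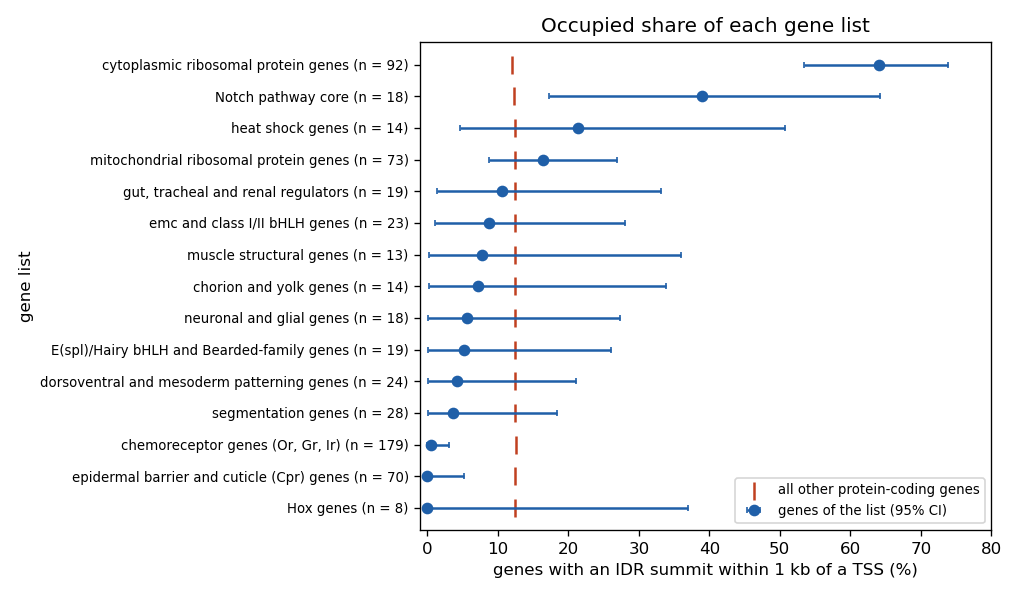
Share (%) of genes with an IDR summit within 1000 bp of a TSS for each of the 15 lists (points, 95% intervals) and for all other protein-coding genes (vertical marks). Cytoplasmic ribosomal protein genes reach 64.1%, and chemoreceptor genes 0.559%.

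The tRNA genes were examined because strongly transcribed loci can attract unspecific signal. An IDR summit lay within 500 bp of 7 of 290 tRNA genes, 2.41% (0.976 to 4.91), against 14.4% of the protein-coding genes, whose longer spans offer more room (two-sided Fisher's exact test, p = 1e-11). In equal windows of 500 bp on either side of each gene's 5' end, chosen after seeing the data, the shares were 2.07% and 9.43% (Fisher's exact test, p = 9.97e-07).

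Several core promoter motifs were more frequent within 100 bp of IDR summits than of weaker summits. The DNA replication-related element (DRE), TATCGATA, was in 5.31% (4.33 to 6.43) against 1.36%, a 3.91-fold difference. Ohler motif 6 was 2.20-fold, the TATA box 1.88-fold, the M1BP motif 2.30-fold, GAGA 1.44-fold and the initiator 1.13-fold as frequent. The E-box CANNTG, the site of bHLH dimers, was in 63.4% (61.2 to 65.6) against 67.3%, 0.943-fold. Adjusted p over 16 motifs was 3.93e-25 for DRE, 2.47e-16 for Ohler 6, 1.46e-14 for TATA and 0.00188 for the E-box (two-sided Fisher's exact test). Smaller differences past the threshold were seen for Pho (0.837-fold), caudal/Abd-B (1.18-fold) and GATA (1.25-fold), each with adjusted p = 0.0397 by Fisher's exact test. Zelda, Su(H), Stat92E, CA repeat, Dorsal and Grainyhead motifs did not pass. Of these calls, that for caudal/Abd-B was lost with either replicate alone and those for Pho and GAGA with replicate 3 alone. With replicate 1 alone DRE was 6.16-fold and M1BP 4.24-fold as frequent, and against flanks 1000 bp away they were 9-fold and 7.56-fold. The M1BP call was lost among promoter peaks (1.04-fold; adjusted p = 0.943), among distal peaks (1.16-fold; adjusted p = 0.720) and within 50 bp (adjusted p = 0.0665, Fisher's exact tests), and the DRE call among distal peaks (1.31-fold). Of the 729 distal IDR peaks only 1 held M1BP and 3 held DRE, too few to tell a difference from none.

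Windows at IDR peaks were poorer in GC, with 37.9% ± 6.55 (SD over 1865 peaks) against 46.4% ± 9.02 at weaker peaks (permutation p = 1e-05, the smallest possible). The 6 chromosomes together had 42.2%, so IDR windows were poorer and weaker windows richer in GC than the genome. Against weaker peaks matched on GC the E-box (1.01-fold), Ohler 6 (1.16-fold) and TATA (0.946-fold) differences were no longer past the threshold, nor were those for M1BP (1.29-fold) and Pho (0.893-fold). GATA and caudal/Abd-B turned to 0.894-fold and 0.827-fold, neither past the threshold, and the initiator to 0.922-fold (adjusted p = 0.0414, Fisher's exact test). DRE stayed at 1.99-fold and GAGA at 1.69-fold (adjusted p = 2.21e-06 and 0.00121, Fisher's exact test). Among promoter peaks also matched on GC, a setting chosen after seeing the data, DRE was at 1.13-fold (adjusted p = 0.744) and GAGA at 1.62-fold (adjusted p = 0.0423, Fisher's exact test). The GAGA difference was not past the threshold within 50 bp (0.908-fold), against flanks (0.955-fold), or among promoter or distal peaks taken alone. It was larger within 250 bp, with 15.5% against 7.82% (1.99-fold; adjusted p = 1.54e-25, Fisher's exact test), not matched on GC. Among the 932 IDR peaks of higher signal the calls for GAGA (1.35-fold), Pho, caudal/Abd-B and GATA were lost, with an adjusted p of 0.115, 0.409, 0.0536 and 0.0536 by Fisher's exact test.

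**Figure D4:**
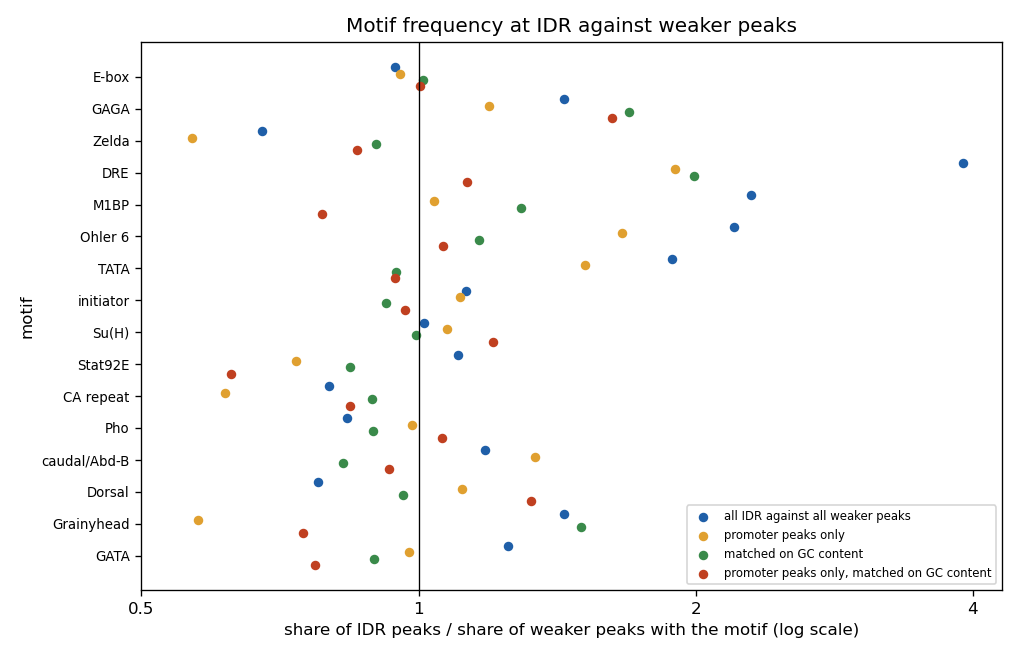
Ratio of the share of IDR peaks to the share of weaker peaks with each of 16 motifs (log scale), for all peaks, promoter peaks, GC-matched peaks and GC-matched promoter peaks. The DRE ratio is 3.91, 1.90, 1.99 and 1.13 in these settings.

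At the emc gene itself (FBgn0000575), which the transgene adds in further copies, the IDR list had 1 peak. It lay at 3L 749455 to 749834, 245 bp downstream of the annotated start of emc (3L 749400 to 753492, forward strand), in sequence that the annotation also assigns to hng3. Its signal of 68.1 ranked 1611 of 1865. The best peak there ranked 1201 in replicate 1 and 1916 in replicate 3. Within 5000 bp of the gene the pooled list had 7 peaks, replicate 1 had 12 and replicate 3 had 10.

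The genes with the most IDR peaks by nearest TSS included transcription factors and a kinase. CHES-1-like, a forkhead gene, had 9, of which 6 were in introns. Hr4 (a nuclear receptor), Myc, Raf, shn and tara had 6 each, all 5 being named because they tied. Their strongest peaks had signals of 165 (Hr4), 109 (Myc), 308 (Raf), 113 (shn) and 462 (tara, intergenic, 3R 16222373 to 16222619). These peaks were not all close to the gene's start. The Myc peak was 9271 bp away, and 202 bp from the start of a long non-coding RNA. The distances were 9998 bp for Hr4 (in an intron), 3184 bp for tara, 2259 bp for Raf and 1203 bp for shn. Over all IDR peaks the median distance to a TSS of a protein-coding gene was 270 bp, and 225 peaks (12.1%) were beyond 5000 bp.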

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

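Predictions for tRNA genes, for promoter location together with GC content, and for GC content at the E-box were written after the values had been seen. Occupancy of tRNA genes and GC matching of motifs had themselves been planned. The comparison of coding exons with weaker peaks of highest signal was chosen after the values had been seen. The other housekeeping families were chosen after the ribosomal protein result.

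Peaks on the heterochromatic and unplaced scaffolds of dm3 were not used in any comparison and appeared in the relaxed lists. Replicate 1 had 209, replicate 3 had 42 and the pooled list had 44. The best-placed of them ranked 1561, 4091 and 2188, and the IDR list had none.

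The first pattern is the occupancy of cytoplasmic ribosomal protein genes. Against abundant transcription of housekeeping genes in general as the whole cause, translation factors, proteasome and oxidative phosphorylation genes together reached 16.1% (11.1 to 22.3), below the lower bound of 53.5% for ribosomal protein genes. These families were chosen after the ribosomal protein result had been seen. Against TSS number and gene length, the highest of 10000 matched lists had 24 occupied genes where 59 were observed. Against unspecific signal at every very strongly transcribed locus, 2.07% of tRNA genes were occupied, and in equal windows 9.43% of protein-coding genes. Reads from repeated tRNA copies may be lost in mapping, which was not tested. RNA polymerase III transcribes tRNA genes, so their share cannot decide about unspecific signal at very active promoters of protein-coding genes. A dependence on transcription above the level of those families stays open, and no biological explanation was tested.

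The second pattern is the motif content of IDR peaks. The DRE odds ratio of 4.07 (3.24 to 5.11) became 1.98 (1.56 to 2.52) among promoter peaks and 2.05 (1.58 to 2.66) with GC matching, which argues against promoter location or GC content alone as the whole cause, but 1.14 (0.883 to 1.48) with both together, where the estimate itself moved close to 1, so both combined may account for it. The E-box odds ratio of 0.844 (0.765 to 0.930) became 1.03 (0.924 to 1.15) with GC matching and 0.882 (0.775 to 1.00) among promoter peaks and 0.902 (0.772 to 1.05) among distal peaks, with intervals that barely reach 1 among promoter peaks, so GC content and promoter location both stay open for the E-box. The 5 control palindromes had a median odds ratio of 1.01 and lay on both sides of the E-box value (0.730 to 1.27), which decides nothing about base composition at large. No biological explanation was tested.

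The third pattern is the scarcity of IDR peaks in coding exons outside promoters. Summits within 500 bp of a TSS were classed as promoter in every set, and coding sequence among them was not counted. An excess of coding exons among weaker peaks is argued against as the whole cause, since the lowest share in 1000 random placements was 11.3% and the IDR share was 0.429%. Against the 1865 weaker peaks of highest signal the share to compare was 3.06%, so much of the contrast lay in weaker peaks of low signal. GC content is argued against as the whole cause by an odds ratio of 0.0860 (0.0425 to 0.174) with GC matching, although the share of coding exons among the matched weaker peaks was itself 4.77% instead of 20.5%. Why weaker peaks, which may include background regions, fell so often in coding exons stays open, and no biological explanation was tested.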

How the results depend on the processing

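Settings on promoter peaks matched on GC, on genomic classes against GC-matched or higher-signal weaker peaks or random placements, equal windows for tRNA genes, and the trimmed lists, were chosen after seeing the data, and causes of changes were not tested unless stated. Among tested results that answer a comparison, 75 alternative values kept direction and side of the threshold, 16 lost the call and 4 reversed. Among single classes, lists and motifs tested besides, 140 were kept, 32 lost the call, 11 gained one and 41 reversed. Among values without a p that answer a comparison, 23 were kept and 14 moved, judged by 1.5 times for counts, by the 95% interval for overlap shares, by the range of random placements, and for the emc rank by the SD between replicates, which at 506 ranks is wide. Over both kinds of tested result, with top-ranked peaks of 1 replicate alone 71 tested values were kept, 9 calls were lost, 1 was gained and 3 values that passed in neither case changed direction. The emc peak could not be placed in dm3, whose gene annotation was not used here, so that alternative was not run. Depth was not given and its limit could not be assessed. Classes past the threshold were 4 of 7 against the higher-signal weaker peaks, where the promoter share to compare was 50.8%. The stricter set left 932 peaks by construction and 2 lists past the threshold, with cuticle genes at 0% (adjusted p = 0.0709, Fisher's exact test). Replicate overlap, replicate 1 in 3 and 3 in 1, was 92.9% and 90.1% with reciprocal overlap of 50%, 89.7% and 86.0% with summits within 100 bp, and 70.1% and 70.9% for top-ranked peaks of both. The Notch list was at 11.1% in the stricter set, 22.2% within 500 bp, 44.4% within 5000 bp, 27.8% by nearest TSS, 38.9% against matched lists, and 22.2% to 33.3% with 1 replicate. Motifs past the threshold numbered 6 among promoter peaks, 6 among distal peaks, 3 with GC matching, 4 against flanks and 2 with GC-matched promoter peaks, against 10 in all peaks. The E-box was 0.996-fold within 250 bp, 0.955-fold at promoter peaks, 0.967-fold at distal peaks, 0.957-fold against flanks, 1.01-fold with GC matching and 1.00-fold with GC-matched promoter peaks. DRE was 1.31-fold at distal peaks (3 of 729 windows), 1.13-fold at GC-matched promoter peaks and 9-fold against flanks. With GC matching, and with GC-matched promoter peaks, Ohler 6 was 1.16-fold and 1.06-fold, TATA 0.946-fold and 0.944-fold, the initiator 0.922-fold and 0.967-fold, caudal/Abd-B 0.827-fold and 0.929-fold, and GATA 0.894-fold and 0.772-fold. GATA was also 0.976-fold at promoter peaks and 0.922-fold against flanks. GAGA was 0.908-fold within 50 bp, 0.955-fold against flanks and 1.99-fold within 250 bp. M1BP was 1.04-fold at promoter peaks, 1.16-fold at distal peaks (1 of 729 windows), 7.56-fold against flanks and 0.786-fold at GC-matched promoter peaks, where Pho was 1.06-fold. Lists and motifs past the threshold neither here nor in all peaks also changed direction. By nearest TSS the share was 12.5% for Hox, 20.8% for dorsoventral and mesoderm, 21.1% for gut, 11.1% for neuronal and 6.85% for mitochondrial ribosomal protein genes. It was 36.8% for E(spl) genes within 5000 bp, and in the stricter set 10.5% for gut, 7.69% for muscle and 7.14% for chorion and yolk genes. Some passed in certain settings only (adjusted p, Fisher's exact test): Su(H) 1.24-fold within 250 bp (0.00524), Stat92E 1.58-fold at distal (0.00667) and 0.626-fold at GC-matched promoter peaks (0.0423), Dorsal 0.315-fold at distal peaks (0.0224) and 0.656-fold within 250 bp (0.00335), CA repeat 0.554-fold in the stricter set (0.00353), 0.593-fold within 50 bp (0.0101) and 0.616-fold at promoter peaks (0.00808), and Zelda 0.484-fold with replicate 3 alone (0.0206). Su(H) was 0.980-fold in the stricter set, 0.653-fold within 50 bp, 0.898-fold at distal peaks, 0.995-fold with GC matching, 0.955-fold against flanks and 0.877-fold to 1.09-fold with 1 replicate. Stat92E was 0.737-fold at promoter peaks, 0.842-fold with GC matching, 0.929-fold against flanks and 0.992-fold to 1.22-fold with 1 replicate. CA repeat was 1.10-fold within 250 bp and 1.04-fold at distal peaks. Dorsal was 1.02-fold in the stricter set, 1.11-fold at promoter peaks and 1.33-fold at GC-matched promoter peaks. Grainyhead was 0.394-fold in the stricter set (1 of 932 windows), 0.576-fold at promoter peaks (2 of 1136), 0.750-fold at GC-matched promoter peaks (2 of 1056) and 0.875-fold to 1.43-fold with 1 replicate. Counts this small cannot show a change. No paired analysis was possible because all samples form 1 group.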

Other observations

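The families in the first paragraph were chosen after the ribosomal protein result had been seen, and the test of first introns was set down before its value was known. Outside the ribosomal proteins, 12 of 52 translation initiation and elongation factor genes were occupied, 23.1% (12.5 to 36.8), among them eEF1alpha1, eIF4A and eIF3a (Fisher's exact test, unadjusted p = 0.0313, 3 families tried). Oxidative phosphorylation genes had 13 of 80 (16.2%), including ATPsynC and COX5A, and proteasome genes 4 of 48 (8.33%), Prosalpha3, Rpn13, Rpn5 and Rpn6 (Fisher's exact test, p = 0.305 and 0.513). These names were picked after their values were seen.

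The genes with the most intronic IDR peaks, named here after their values were seen, held few of the 523: 7 lay in introns of Raf, 6 each in CG1677, CHES-1-like and Hr4, and 5 each in shn and simj. A hypothesis was that intronic IDR peaks favour first introns. Of 523 intronic IDR peaks in protein-coding genes 395 were in a first intron of some transcript, 75.5%, against 56.5% of 8904 weaker intronic peaks, an odds ratio of 2.38 (1.94 to 2.92; Fisher's exact test, p = 1.48e-18). This is consistent with the hypothesis, though distance to the TSS beyond 500 bp was not matched and could account for it.

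Of 10 E-box forms 5 were less frequent at IDR peaks past the threshold (CACCTG, CAGATG, CAAGTG, CAACTG and CACATG), and CATATG alone was more frequent. CACCTG was in 109 of 1865 IDR windows (5.84%) against 2724 of 27229 weaker windows, and CATATG in 7.40% against 5.33% (adjusted p = 5.57e-09 and 0.000902 over the forms, Fisher's exact test), neither matched on GC. Of the 22 bHLH genes without emc, 1 was occupied, and without Cp190 and Cp110 the chorion and yolk list had 0 of 12.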
